A study of Homo sapiens with 9 samples.

How the data were processed

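RNA from Caco-2 cells was read on 9 Affymetrix arrays, 1 per sample, after 12 days with linoleic acid (LA), trans-10,cis-12 conjugated linoleic acid (t10c12 CLA) or cis-9,trans-11 conjugated linoleic acid (c9t11 CLA), with 3 arrays in each group. Groups were taken from the sample descriptions. The labels name total RNA extracted with Trizol and labelled with biotin. They do not say whether the arrays of a group come from separate cultures, so the p-values below measure the spread between these samples, which may be technical. Doses, the state of the cell layer and the day of processing are not given in the sources used here.

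The deposited values are 1 intensity per probe set and array. Per the submitters' processing notes they were made with GCRMA, a method that corrects probe signals for background by their sequence, normalizes between arrays and summarises the probes of each set. Its version and settings, and whether all 9 arrays went through 1 run, are not given in the sources used here. The deposited intensities run from 2.42 to 32556 and are therefore on a linear scale, and log2 was taken here. The table holds 54675 probe sets, of which 62 are Affymetrix controls. In the platform annotation 41091 probe sets name exactly 1 gene, 1801 name several and 11721 name none, and only the first kind was used for genes. Gene symbols were matched to a RefSeq gene table (assembly GRCh38.p14), which covered 41037 of the 41091 probe sets and changed 0 symbols. Genome coordinates are not used here, since the array annotation names no build.

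For each of the 19775 genes the probe set with the highest mean over the 9 arrays was kept. Genes with a log2 value of at least 4 (intensity 16) on at least 3 of the 9 arrays were tested, which left 11194. A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation that follows the intensity trend. The 3 pairwise contrasts and a moderated F test over the groups were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. Rose, fell, higher and lower refer to genes past that threshold. Errors of log2 fold changes are the moderated standard errors (SE), errors of intensities are standard deviations (SD), and n is 3 arrays per group throughout. The number of arrays limits the precision.

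The groups, the filter, the test, 25 gene lists and the rule for naming genes were fixed before the data were examined. Of the 522 genes on the lists, 467 are on the array under a usable symbol. Each list was tested in each contrast with limma's camera at its preset correlation between genes of 0.01, adjusted over the 25 lists of a contrast. Beside it stand camera with an estimated correlation, which called 0 lists in each contrast, and fry, which asks whether the genes of a list move on balance 1 way and compares them with no other genes. At an unadjusted p under 0.05, camera with an estimated correlation passed 3 lists for t10c12 CLA against LA, 3 for c9t11 CLA against LA and 1 for t10c12 CLA against c9t11 CLA. Counts called adjusted over the list alone apply the Benjamini-Hochberg method to the members of that list only.

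Named genes are those past the threshold whose 3 values in one group all lie above the 3 of the other, the 10 with the largest rise and the 10 with the largest fall in each contrast. Added to these are up to 4 members with the smallest p of each list called by camera or holding at least 3 members past the threshold, and up to 2 members of other lists, given as values without a verb of change. A gene named in one contrast may be given in the others.

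The fit was tested on simulated arrays with the 11194 genes, their means and spreads, and 200 genes changed by known amounts. For t10c12 CLA against LA it recovered 55.2% of the genes changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold, with 6.2% of the calls false. For c9t11 CLA against LA the shares were 44.8%, 95.5% and 100%, with 4.2% false. For t10c12 CLA against c9t11 CLA they were 46.3%, 94.0% and 100%, with 4.8% false. The simulated noise was independent between genes and arrays, without shifts of scale, a pattern among dim genes or pairing. These shares therefore test the fit and do not measure the false share among the real calls. Both comparisons against LA share the 3 LA arrays, so the agreement between them was set beside 100 simulated draws of unchanged groups that share their control.

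The sample titles number 2 arrays of each CLA group 2 and 3 and the LA arrays 1 to 3, and the remaining array of each CLA group has no number. The deviations of arrays from their group means correlated at 0.161 to 0.359 for the 6 pairs of arrays with the same labelled number, all over 0.1, so numbers 2 and 3 were taken to pair arrays across groups. With the unnumbered arrays taken as number 1, arrays with different numbers correlated at -0.416 to 0.177, which overlaps that range at its lower end, and 6 of the 9 arrays correlated best with an array of their own number. The unnumbered arrays correlated at 0.298 with each other and at 0.025 and 0.017 with LA replicate 1. This pairing comes from the titles and the values, since the labels do not say what a number marks. The fit fixed before the data were examined has no replicate block, and a fit with these numbers as a block uses the 6 arrays numbered 2 and 3 and leaves out the other 3.

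The alternatives were other filters on dim genes, the mean of a gene's probe sets, each probe set on its own, other models of the spread, array weights, quantile normalization, centring of each array on its median over the genes tested, the 6 arrays of a contrast alone, a replicate block, other thresholds, and leaving out each array. Two-sided exact permutation tests compared the array controls between groups. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Probe sets that name several genes or none were left out of the comparisons.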

Results

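Caco-2 is an established human colon adenocarcinoma line whose confluent layers take on features of absorptive intestinal cells. The cells were given LA, described as the parent and control fatty acid, or 1 of 2 CLA isomers for 12 days, and each of the 3 groups holds 3 arrays. The isomers differ from LA and from each other in the place and geometry of the double bonds. The arrays correlated at r of 0.987 to 0.992 within groups and 0.959 to 0.990 between groups across the 11194 genes tested, which are not independent replicates. The median intensity of these genes lay between 151 and 165 on every array. A moderated F test found that 3212 genes (28.7%) differed among the 3 fatty acids. The first principal component held 54.9% of the variance, with the t10c12 CLA arrays at 27.7 to 37.0, the LA arrays at -13.1 to -1.06 and the c9t11 CLA arrays at -27.5 to -21.3.

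The first comparison asks how expression in cells given t10c12 CLA differed from that in cells given LA. LCT, which encodes lactase, rose from an intensity of 96.7 ± 14.1 to 690 ± 48.7 (SD, n = 3), a log2 change of 2.84 (SE 0.15). KRT20, a keratin of mature intestinal epithelium, rose by 3.03 (SE 0.29), the bile acid exporter subunit SLC51A by 2.87 (SE 0.37) and the apolipoprotein APOA4 by 2.73 (SE 0.40). In the other direction SI, which encodes sucrase-isomaltase, fell from 3068 ± 281 to 407 ± 338, a change of -3.69 with a wide error (SE 0.78), which was -2.40 without t10c12 CLA replicate 1, and the fibrinogen chain FGA fell from 1550 ± 522 to 198 ± 26.0, a change of -2.91 (SE 0.23).

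In all, 1601 of the 11194 genes (14.3%) passed the threshold, 664 higher and 937 lower with t10c12 CLA, and 148 of them rose and 185 fell by at least 2-fold. With centred arrays 1629 passed, 790 higher and 839 lower (51.5% lower, against 58.5%), and 161 rose and 166 fell by at least 2-fold. The largest rise was that of UCHL1, a ubiquitin hydrolase best known from neurons, at 4.60 (SE 0.24, adjusted p 5.12e-06), from 39.1 ± 7.33 to 980 ± 340. MLLT11 rose by 3.52, the NRF2 target PIR by 2.79, the cell surface protein gene CEACAM7 by 2.75, the collagenase MMP1 by 2.72 and the copper carrier CP by 2.56. The largest fall was that of the laminin chain LAMA1 at -3.96 (SE 0.25, adjusted p 1.44e-05). HEPACAM2 changed by -3.16, the plasma protein gene APOH by -3.12, MALRD1 by -2.92, APELA by -2.71, REG4 by -2.52, the sulfotransferase CHST9 by -2.43 and IRAG2 by -2.40. With t10c12 CLA the mean intensities of LAMA1, HEPACAM2, MALRD1, CHST9 and IRAG2 lay under 16, close to background, so the sizes of these falls are uncertain.

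**Figure D1:**
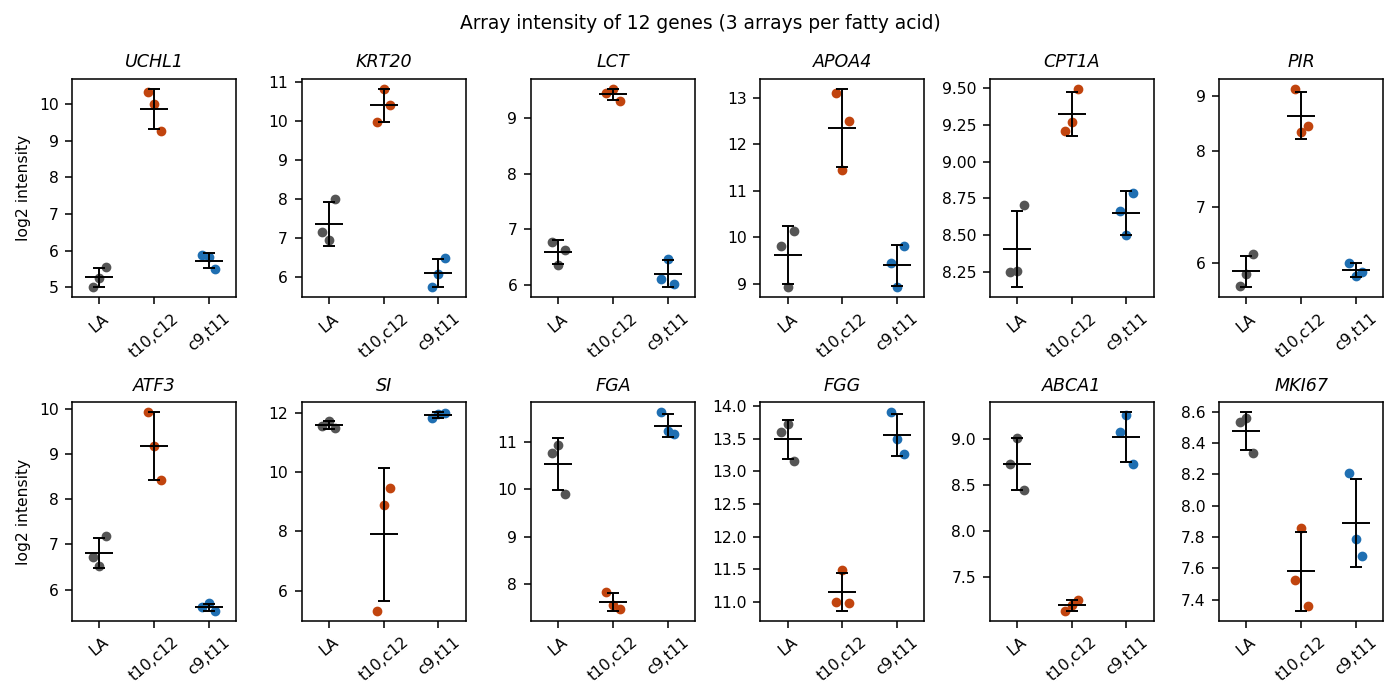
Points give the log2 intensity of single arrays for 12 named genes, grouped by fatty acid on the horizontal axis, with the mean and SD of the 3 arrays of each group in black; the vertical axes differ between genes. For LCT, UCHL1 and PIR the t10c12 CLA arrays stand above all others, and for FGA, FGG and ABCA1 below all others.

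Of 17 measured genes of cholesterol synthesis and uptake, 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them the last-step enzyme DHCR7 at 0.74 (SE 0.09), the sterol sensor INSIG1 at 0.94 (SE 0.14), LSS at 0.77 (SE 0.16) and HSD17B7 at 0.51 (SE 0.11). Camera placed the list higher (adjusted p 4.21e-06; adjusted p = 0.297 with an estimated correlation). Of 14 genes of fatty acid synthesis and desaturation, 5 rose (5 adjusted over the list alone), including ME1 at 1.15, HSD17B12 at 0.67, ACLY at 0.46 and the desaturase SCD at 0.49 (adjusted p 0.000884; adjusted p = 0.265 with an estimated correlation). Of 16 genes of fatty acid oxidation and PPAR targets, 6 rose (6 adjusted over the list alone), with ACSL1 at 0.99, CPT1A, which lets fatty acids into mitochondria, at 0.92, the lipid droplet coat PLIN2 at 0.80 and ACADVL at 0.56 (adjusted p 0.000271; adjusted p = 0.297 with an estimated correlation).

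The 19 genes of triglyceride and lipoprotein assembly moved both ways, 4 higher and 3 lower, and the list was not called (adjusted p 0.135). APOA4 and MGLL, the latter at 1.17, rose, while APOE fell by 0.74 and the acyltransferase GPAM by 0.82. Of 10 sterol efflux genes and LXR targets 2 rose and 4 fell (adjusted p 0.170). The cholesterol exporter ABCA1 fell from 430 ± 83.6 to 147 ± 6.01, a change of -1.53 (SE 0.16), and MYLIP fell by 0.79 and NPC2 by 0.32, while NPC1 rose by 0.59.

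The brush border and absorption list held 20 measured genes, of which 6 rose and 1 fell (9 and 1 adjusted over the list alone), and camera placed it higher (adjusted p 0.000319; adjusted p = 0.191 with an estimated correlation). Besides LCT and KRT20, the amino acid transporter SLC7A9 rose by 1.78 (SE 0.15) and the aminopeptidase ANPEP by 1.61 (SE 0.22), and SI was the member that fell. Of 22 cell junction genes 6 rose (6 adjusted over the list alone), with the desmosomal cadherins DSG2 at 0.63 and DSC2 at 0.62 and the claudins CLDN4 at 0.74 and CLDN2 at 1.25. That list passed by little (adjusted p 0.0301; adjusted p = 0.376 with an estimated correlation) and was no longer called without t10c12 CLA replicate 1 (0.0918), LA replicate 2 (0.0539) or LA replicate 3 (0.0743). Among 11 intestinal transcription factors KLF4 rose by 0.65, and GATA6 at -0.67 and FOXA1 at -1.17 fell (list adjusted p 0.614). Of 14 genes of calcium transport and the vitamin D response 3 rose, MYLK by 1.40, the calcium-binding protein gene S100G by 2.41 (SE 0.52) and ATP2A2 by 0.37, and the list missed the threshold (adjusted p 0.0563).

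Of 20 NRF2 and oxidative stress genes 8 rose and 2 fell (11 and 2 adjusted over the list alone), with PIR, the glutathione synthesis subunit GCLM at 1.55 (SE 0.18), SRXN1 at 1.36 and ME1 (adjusted p 4.21e-06; adjusted p = 0.255 with an estimated correlation). Of 23 genes of the unfolded protein and amino acid stress response 6 rose and 0 fell (7 and 0 adjusted over the list alone), with the transcription factor ATF3 at 2.37 (SE 0.30), TRIB3 at 1.54 (SE 0.12), DNAJB9 at 0.69 and the chaperone HSPA5 at 0.58 (adjusted p 4.21e-06; adjusted p = 0.297 with an estimated correlation). Of 18 p53 and apoptosis genes 5 rose and 2 fell (6 and 2 adjusted over the list alone). The cell cycle inhibitor CDKN1A rose by 0.90 and the death receptor TNFRSF10A by 0.75, while SESN1 fell by 0.77 and BCL2L11 by 1.16 (adjusted p 0.00990; adjusted p = 0.338 with an estimated correlation). The glycolysis and hypoxia list of 23 genes was called (adjusted p 0.00995; adjusted p = 0.652 with an estimated correlation), though PFKP at 0.74 was its single member past the threshold (0 adjusted over the list alone). Without t10c12 CLA replicate 1 (0.118), LA replicate 2 (0.256) or LA replicate 3 (0.0553) this call was lost.

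Of 25 measured proliferation genes 16 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 change of -0.62 (adjusted p 1.24e-09; adjusted p = 0.297 with an estimated correlation). MKI67, the gene of the Ki-67 antigen, fell from 357 ± 29.2 to 194 ± 34.6, a change of -0.90 (SE 0.16), the cyclin gene CCNE2 changed by -0.94, RRM2 by -0.98 and the mitotic kinase gene AURKA by -0.55. The liver-type secreted proteins fell too, 6 of 15 (10 adjusted over the list alone), with a median of -0.90 (adjusted p 2.68e-05; adjusted p = 0.297 with an estimated correlation). FGG fell from 11680 ± 2280 to 2316 ± 489, a change of -2.33 (SE 0.19), and RBP4 by 1.13, beside FGA and APOH.

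The other lists were not called. Of 14 xenobiotic genes 6 rose and 4 fell (adjusted p 0.0571), with the efflux pump ABCG2 at 1.10 (SE 0.11), SULT1A1 at 0.94, CYP3A5 at 0.87 and UGT2B17 at -2.23. Of 12 Wnt targets and crypt stem cell genes 2 rose and 3 fell (adjusted p 0.170), with CD44 at 1.19, a size that is uncertain since its mean with LA lay under 16, against ZNRF3 at -0.92, ASCL2 at -0.76 and PROM1 at -0.75. Of 14 interferon response genes 2 rose and 2 fell (adjusted p 0.926), IFIT1 at -2.25, IFI6 at -0.71, IFITM1 at 0.87 and OAS1 at 0.56. Of 16 cytoskeleton and matrix genes 4 rose and 1 fell (adjusted p 0.309), with ITGA6 at 0.74, ITGB4 at 0.61 and TGFBI at -0.77 beside MMP1. Among 12 inflammation genes CFB at -1.12 and IL18 at 0.61 passed the test (adjusted p 0.956), and among 9 metallothionein and zinc genes the zinc importer SLC39A4 at 1.94 did (adjusted p 0.137). For 10 heat shock genes (adjusted p 0.174) and 22 respiratory chain genes (adjusted p 0.940) 0 members passed. Of markers of other cell types, TFF1 at 1.45 and REG4 at -2.52 passed among 6 secretory cell genes (adjusted p 0.323), and COL1A1 at -1.08 among 5 stromal, endothelial and blood cell genes (adjusted p 0.323). Adjusted over the list alone, the higher and lower members numbered 6 and 4 for triglyceride assembly, 2 and 5 for sterol efflux, 8 and 4 for xenobiotic genes, 2 and 3 for Wnt targets, 2 and 2 for interferon genes, 4 and 1 for cytoskeleton genes and 1 and 2 for metallothioneins. Medians, means and test directions differed in sign for the interferon, respiratory chain, cytoskeleton and secretory cell lists.

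The 3 values of each group did not overlap for 1580 of the 1601 genes called, and for 31.0% of all genes tested, where chance gives 10%. Without t10c12 CLA replicate 1 the count was 1001 and without LA replicate 2 it was 1021. With a replicate block on the arrays numbered 2 and 3, OAS1 at 0.46 (adjusted p 0.0788) and ITGB4 at 0.46 (adjusted p 0.0762) were not called, while the triglyceride (adjusted p 0.0276) and calcium (adjusted p 0.0393) lists were placed higher (adjusted p = 0.36 and adjusted p = 0.471 with an estimated correlation). SI at -2.42, CD44 at 0.76 and COL1A1 at -0.61 passed with smaller changes. Fry with that block missed the threshold for the cholesterol, fatty acid synthesis and cell junction lists (adjusted p 0.063, 0.0863 and 0.0863). It also missed it for the unfolded protein, p53 and liver-type lists (0.1, 0.469 and 0.063). It passed for fatty acid oxidation, brush border, proliferation, NRF2 and glycolysis (0.0294 to 0.0438). Camera on centred arrays with that block did not call the p53 list (adjusted p 0.0597). The Wnt list was then placed lower (adjusted p 0.0359, or adjusted p = 0.44 with an estimated correlation). With that block the higher and lower members numbered 7 and 0 for glycolysis and hypoxia, HK2 at 0.95, EGLN3 at 0.75 and VEGFA at 0.31 among them, 8 and 2 for the brush border, 6 and 2 for cell junctions, 2 and 4 for intestinal transcription factors, 1 and 5 for Wnt targets, 1 and 2 for interferon genes, 2 and 3 for cytoskeleton genes, 1 and 2 for metallothioneins and 0 and 1 for heat shock genes.

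**Figure D2:**
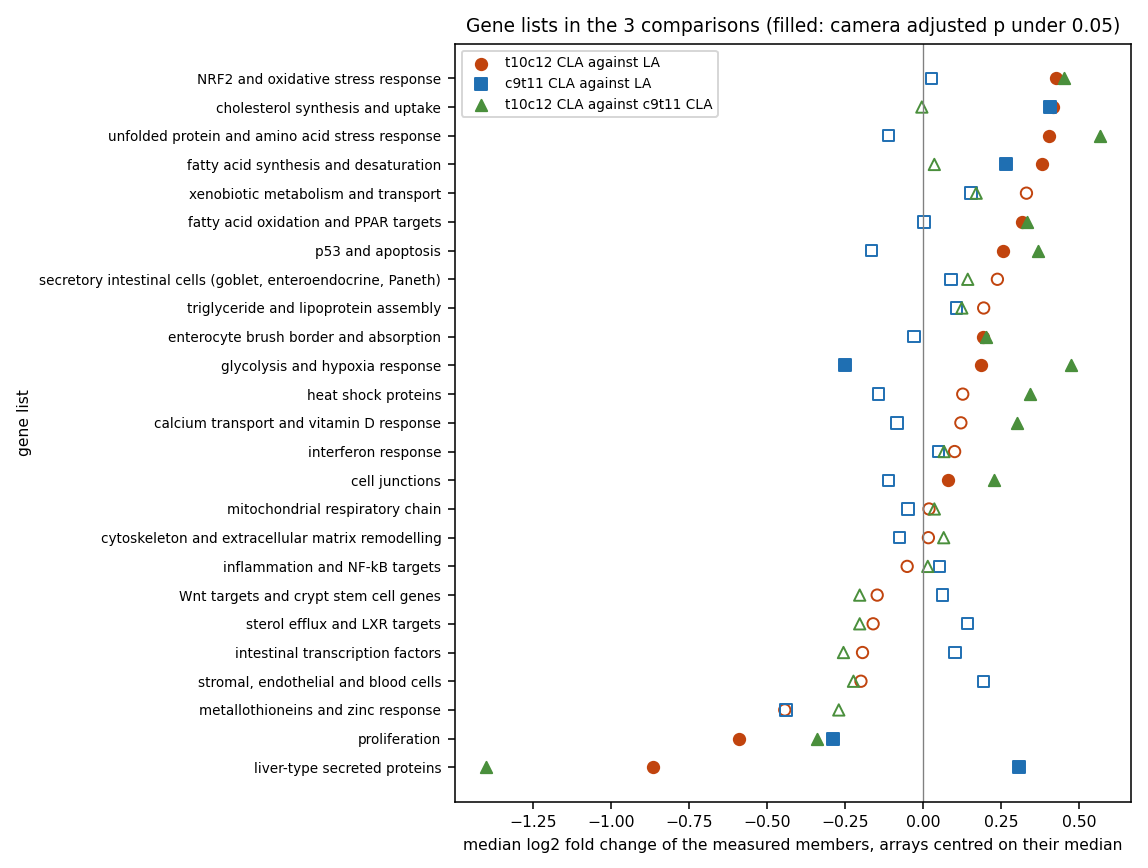
Each row is a gene list and the horizontal axis gives the median log2 fold change of its measured members after each array was centred on its median; circles, squares and triangles stand for the 3 comparisons, and filled symbols for lists called by camera at its preset correlation on the centred arrays. Proliferation genes lie below 0 in each comparison, and liver-type secreted proteins lie at -0.87 for t10c12 CLA against LA and at 0.31 for c9t11 CLA against LA.

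The second comparison sets cells given c9t11 CLA against cells given LA. Among the largest changes were those of dim genes. APLP1, an amyloid precursor-like protein gene, rose from 5.71 ± 0.19 to 18.7 ± 1.52 (SD, n = 3), and the potassium channel gene KCNN1 fell from 24.9 ± 0.35 to 5.02 ± 0.29. Among brighter genes, 2 of 17 cholesterol genes rose, LSS and HMGCS1, and 5 of 25 proliferation genes fell, AURKA and BUB1 among them. Over all genes tested the median log2 change was -0.13 and the c9t11 CLA arrays had the lowest medians, so changes below are given as fitted, with every array centred on its median (centred), or both.

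In all, 491 genes (4.4%) passed in the fit without a replicate block, 88 higher and 403 lower (82.1% lower). With the replicate block on the arrays numbered 2 and 3, 812 passed, 95 higher and 717 lower (88.3% lower), of which 327 were also among the 491. With the block and centred arrays together, chosen after seeing the data, 133 passed, 45 higher and 88 lower (66.2% lower). With centred arrays 226 passed, 109 higher and 117 lower (51.8% lower), of which 203 were also called without centring, and after quantile normalization 216 passed, 125 higher and 91 lower (42.1% lower). Genes with a mean log2 below 5 made up 39.3% of the calls. Of these dim genes 11.2% were called, against 2.8% of the genes between 6 and 8 and 2.9% of those above 8. With the filter raised to a log2 of 6 and no rescaling, 71 genes passed, 2 higher and 69 lower. With that filter and quantile normalization together, chosen after seeing the data, limma called 0 of 8263 genes, while 1047 had an unadjusted p under 0.05. Leaving out single arrays gave 80 calls (without c9t11 CLA replicate 2), 101 (without LA replicate 3), 152 (without c9t11 CLA replicate 3), 182 (without LA replicate 1) and 228 (without c9t11 CLA replicate 1).

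Dim probe sets also stood apart on the c9t11 CLA arrays. Of 27969 probe sets too dim to test on any array, centred on the median of each array, 36.8% had their 3 c9t11 CLA values all above or all below the other 6 arrays. The same share was 5.18% for the t10c12 CLA arrays and 2.47% for the LA arrays, and chance gives 2.38%. Among the 4274 genes with a mean log2 above 8 the t10c12 CLA arrays stood apart most often, at 26.4%, against 11.02% for c9t11 CLA and 3.51% for LA.

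**Figure D3:**
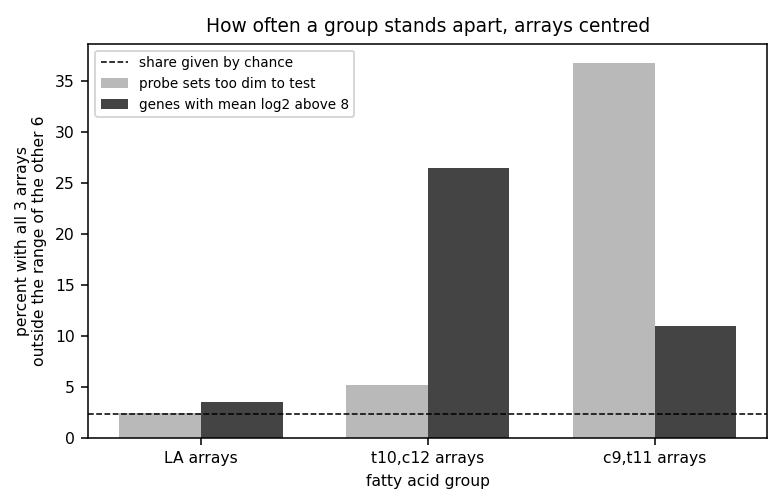
Bars give the percent of probe sets (light) or bright genes (dark) whose 3 values in 1 group lie all above or all below those of the other 6 arrays, by group, with arrays centred; the dashed line is the share given by chance. The c9t11 CLA arrays stand apart at 36.8% of the dim probe sets and 11.02% of the bright genes.

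Of the 41 named genes called in this comparison 30 kept their call under both centring and quantile normalization. Besides APLP1 at 1.71 (centred 1.81), the rises were led by the heparan sulfate carrier GPC1 at 1.40 (centred adjusted p 0.00388), SLC22A9 at 1.27 (centred 1.37), the hepatokine FGL1 at 1.19 (centred 1.29) and the glucose-6-phosphatase gene G6PC1 at 1.10 (centred 1.21). NEU4, MAN1C1, SYNE1 and SEC16B followed with centred values of 1.17, 1.17, 1.15 and 1.15, and FAM161B, at a centred 1.12, lost its call on centring. Besides KCNN1 at -2.31 (centred -2.21), the falls were led by the arginase gene ARG2 at -1.89 (centred -1.79, SE 0.34), GPR132 at -1.71 (centred -1.60) and SLC35G2 at -1.55 (centred -1.45). MPV17L2, CEP131, TCF15, ATOSB, the pseudogene BTF3P12 and NIN had centred changes of -1.42, -1.36, -1.36, -1.29, -1.28 and -1.24. In 16 of the 41 genes one of the 2 groups had a mean intensity under 16, KCNN1, APLP1 and GPR132 among them, and the sizes of those changes are uncertain.

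Camera called 8 lists in this comparison and 5 of them on centred arrays. Camera with an estimated correlation called 0 lists, and fry called 0 of these 8. Fry's adjusted p was 0.137 for cholesterol, 0.228 for fatty acid synthesis, 0.205 for proliferation, 0.215 for glycolysis and 0.501 for liver-type proteins. For triglyceride assembly, xenobiotic genes and heat shock genes it was 0.852, 0.803 and 0.137. The estimated correlation between the cholesterol genes was 0.494, above the preset one. The calls below rest on the preset correlation alone. Cholesterol synthesis and uptake was higher (adjusted p 6.79e-13, centred 2.71e-11; adjusted p = 0.297 with an estimated correlation), with 2 of 17 members past the threshold and 6 adjusted over the list alone. LSS rose from 375 ± 21.8 to 629 ± 57.7, a change of 0.74 (SE 0.16, centred 0.84), and HMGCS1, the first enzyme committed to the pathway, by 0.51 (SE 0.12, centred 0.61), though HMGCS1 was not called with the mean of its probe sets (0.42). EBP at 0.35 and DHCR7 at 0.34 missed the threshold and passed it on centring, at 0.45 and 0.44. Fatty acid synthesis and desaturation was higher (adjusted p 0.00220, centred 0.00385; adjusted p = 0.297 with an estimated correlation) with 1 of 14 members past it, the desaturase gene FADS2 at 0.67 (centred 0.77), which is dim. Proliferation was lower (adjusted p 0.000533, centred 3.37e-05; adjusted p = 0.660 with an estimated correlation) with 5 of 25 members past the threshold (7 adjusted over the list alone) and a median of -0.39 (centred -0.29). AURKA fell by 0.58 (centred -0.48), BUB1 by 0.80 (centred -0.70), CCNA2 by 0.68 (centred -0.57) and CDK1 by 0.51 (centred -0.41). CCNA2 and CDK1 lost their calls on centring, and AURKA after quantile normalization. Without c9t11 CLA replicate 3 the proliferation list had an adjusted p of 0.0746.

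Glycolysis and hypoxia genes were lower as a list (adjusted p 0.00488, centred 0.00332; adjusted p = 0.664 with an estimated correlation), with 2 of 23 members past the threshold (8 adjusted over the list alone). These were the glucose transporter SLC2A1 at -0.85 (centred -0.75) and VEGFA at -0.41 (centred -0.30), and both lost their calls on centring. That list was not called without LA replicate 1 (0.383) or c9t11 CLA replicate 2 (0.0794). Liver-type secreted proteins were higher as a list (adjusted p 0.000102, centred 0.00147; adjusted p = 0.570 with an estimated correlation) with 0 of 15 members past the threshold, FGA standing at 0.81 (SE 0.23, centred 0.91) and FGB at 0.56 (SE 0.24, centred 0.66). Triglyceride and lipoprotein assembly (adjusted p 0.0342, centred 0.0566; adjusted p = 0.297 with an estimated correlation), xenobiotic metabolism (adjusted p 0.0342, centred 0.0574; adjusted p = 0.524 with an estimated correlation) and heat shock proteins (adjusted p 0.0342, centred 0.0574; adjusted p = 0.621 with an estimated correlation) lost their calls on centring. In each of these 3 lists 0 members passed limma's test over all genes, and adjusted over the list alone 3 heat shock genes were lower and 0 members of the others passed. The triglyceride list was not called without LA replicate 1 (0.0519), LA replicate 3 (0.0922) or c9t11 CLA replicate 2 (0.144). Heat shock genes were not called without LA replicate 3 (0.267), c9t11 CLA replicate 1 (0.0518) or c9t11 CLA replicate 2 (0.174). Xenobiotic genes were not called without LA replicate 1 (0.123), LA replicate 3 (0.0949), c9t11 CLA replicate 1 (0.0518) or c9t11 CLA replicate 3 (0.0746).

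Of the lists not called, cell junctions held 2 members past the threshold, DSG2 at a centred -0.43 and OCLN at a centred -0.27, the latter not called on centred arrays (list adjusted p 0.0755, with 6 lower adjusted over the list alone). Other members past the threshold were IFITM1 at a centred -1.20, PLAUR at -1.10, NKD1 at -0.85, VIM at -0.70, CXCL3 at 0.83 and BCL2 at 0.84. KRT20 at a centred -1.17, ATF3 at -1.09, CCL20 at -0.65 and ITPR3 at -0.38 were not called on centred arrays. For sterol efflux, intestinal transcription factors, fatty acid oxidation, NRF2, metallothionein, respiratory chain, secretory cell and stromal lists 0 members passed, with list adjusted p of 0.0741, 0.184, 0.550, 0.752, 0.218, 0.257, 0.257 and 0.257. The brush border, Wnt, calcium, unfolded protein, inflammation, interferon, p53 and cytoskeleton lists had adjusted p of 0.897, 0.443, 0.443, 0.257, 0.0741, 0.752, 0.752 and 0.608. Adjusted over the list alone, 7 p53 and apoptosis genes and 4 interferon genes were lower. Camera compares a list with all other genes, which lay lower on these arrays, and its direction, the median and the mean of a list can differ in sign. Among the lists called they did for triglyceride assembly, placed higher at a median near 0. Among the others they did for the fatty acid oxidation, Wnt, NRF2, inflammation, interferon, secretory cell and stromal lists.

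With the replicate block, 21 of the 25 proliferation genes were lower (7 on centred arrays), 7 of the 17 cholesterol genes higher (6 centred) and 5 of the 23 glycolysis and hypoxia genes lower (1 centred). EBP at 0.41 (adjusted p 0.0224, centred 0.0372) and DHCR7 at 0.39 (adjusted p 0.0442, centred 0.0455) passed with the block, and FGA at 0.78 (adjusted p 0.0453) did so only without centring (0.0794). FADS2 at 0.62 (adjusted p 0.0612), VEGFA at -0.30 (adjusted p 0.0524), CXCL3 at 0.67 (adjusted p 0.0897), CCL20 at -0.67 (adjusted p 0.0797) and BCL2 at 0.57 (adjusted p 0.0724) were not called with the block, nor were they with the block on centred arrays. Of the 41 named genes called, 36 kept the call with the block and 26 with the block on centred arrays, where SYNE1, KRT20, CCNA2, NKD1, DSG2, OCLN, ITPR3, ATF3, VIM and PLAUR lost it as well (adjusted p 0.0553 to 0.137). The block ended the call of the xenobiotic list (adjusted p 0.169, centred 0.222). It added the sterol efflux list, placed higher with 0 of 10 members past the threshold (adjusted p 0.0233, centred 0.0133), and the unfolded protein and amino acid stress list, placed lower with 7 of 23 members past the threshold, or 2 on centred arrays (adjusted p 0.0118, centred 0.00974). For both lists it was adjusted p = 0.526 with an estimated correlation, centred or not. With the block on centred arrays the triglyceride list was placed higher (adjusted p 0.0168) and the heat shock list lower (adjusted p 0.00974). Each again had adjusted p = 0.526 with an estimated correlation. On uncentred and on centred arrays, 3 and 0 heat shock genes, 3 and 0 Wnt targets, 3 and 1 NRF2 genes, 3 and 1 interferon genes, 2 and 1 secretory cell genes and 2 and 0 brush border genes were lower with the block. A further 2 brush border genes and 1 gene each of the interferon, triglyceride and inflammation lists were higher in both, 1 gene each of the liver-type and fatty acid oxidation lists was higher only without centring, and 1 gene each of the triglyceride, xenobiotic, p53 and respiratory chain lists was lower only without centring.

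The third comparison sets the 2 isomers directly against each other at the same 12 days, and the labels used here give no dose. KRT20 was higher with t10c12 CLA by a log2 of 4.30 (SE 0.29), at 1401 ± 404 against 70.6 ± 17.9 (SD, n = 3), and UCHL1 by 4.14 (SE 0.24). ATF3 was higher by 3.56 (SE 0.30) and LCT by 3.23 (SE 0.15). SI differed by -4.02 (SE 0.78), or by -2.79 with the replicate block on the arrays numbered 2 and 3, FGA by -3.72 (SE 0.23) and APOH by -3.33 (SE 0.36), all lower with t10c12 CLA.

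In all, 3458 genes (30.9%) differed, 2313 higher and 1145 lower with t10c12 CLA (33.1% lower). With centred arrays 3170 differed, 1736 higher and 1434 lower (45.2% lower), and after quantile normalization 3088, 1533 higher and 1555 lower (50.4% lower). At least 2-fold differences numbered 385 higher and 226 lower, or 330 higher and 281 lower on centred arrays. Others among the largest were SLC51A at 3.93, CEACAM7 at 3.76, MLLT11 at 3.73, ARG2 at 3.26, C17orf78 at 3.26 and the RNA-editing enzyme gene APOBEC1 at 3.24. On the lower side stood MALRD1 at -3.90, LAMA1 at -3.72, HEPACAM2 at -3.57, APELA at -3.18, the thrombin inhibitor gene SERPIND1 at -2.96, UGT2B17 at -2.92 and GPC5 at -2.90. Of the genes with a mean log2 below 5, 34.7% were called, and 33.5% of those above 8. The c9t11 CLA arrays, which stood apart at 36.8% of the probe sets too dim to test, also enter this comparison and the F test. How far the handling of these arrays adds to both counts was not tested and cannot be told apart from the isomer. The dimmer group of C17orf78, APOBEC1, MALRD1, LAMA1, HEPACAM2 and GPC5 had a mean under 16, so the sizes of these differences are uncertain.

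Camera called 9 lists. Higher with t10c12 CLA were 14 of 23 genes of the unfolded protein and amino acid stress response (15 adjusted over the list alone), including TRIB3 at 1.61 (SE 0.12), CEBPB at 1.04 and HSPA5 at 0.73 (adjusted p 8.36e-05; adjusted p = 0.468 with an estimated correlation). Of 23 glycolysis and hypoxia genes 13 were higher (17 adjusted over the list alone), including SLC2A1 at 1.29 (SE 0.18), HK2 at 1.60, PFKP at 1.22 and VEGFA at 0.69 (adjusted p 0.000497; adjusted p = 0.555 with an estimated correlation). Of 20 NRF2 genes 13 were higher and 2 lower (13 and 2 adjusted over the list alone), including PIR at 2.77, SRXN1 at 1.65 and TXNRD1 at 1.03 (adjusted p 0.00220; adjusted p = 0.417 with an estimated correlation). Of 22 cell junction genes 11 were higher and 1 lower (14 and 1 adjusted over the list alone), including DSG2 at 1.16 (SE 0.08), CLDN4 at 1.22, CLDN7 at 0.94 and DSC2 at 0.84 (adjusted p 0.0126; adjusted p = 0.468 with an estimated correlation).

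Of 16 fatty acid oxidation genes and PPAR targets 10 were higher (11 adjusted over the list alone), including PLIN2 at 1.18, the fatty acid binding protein gene FABP1 at 1.32, CPT1A at 0.67 and HADHA at 0.38 (adjusted p 0.0147; adjusted p = 0.506 with an estimated correlation). Of 20 brush border genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone), including SLC7A9 at 1.88 and ANPEP at 1.82 (adjusted p 0.0345; adjusted p = 0.417 with an estimated correlation). Of 10 heat shock genes 6 were higher (6 adjusted over the list alone), including HSP90AB1 at 0.60 and HSP90AA1 at 0.47 (adjusted p 0.0334; adjusted p = 0.555 with an estimated correlation). The calls of these 3 lists were lost without t10c12 CLA replicate 3 (0.108, 0.0990 and 0.0577) and without c9t11 CLA replicate 1 (0.0518, 0.0710 and 0.0518), and that of heat shock genes also without c9t11 CLA replicate 2 (0.0686). Liver-type secreted proteins were lower, 10 of 15 (12 adjusted over the list alone), with FGG at -2.40 and FGB at -1.46 (adjusted p 1.57e-07; adjusted p = 0.417 with an estimated correlation). Proliferation was lower as a list (adjusted p 0.00492; adjusted p = 0.672 with an estimated correlation) with 4 of 25 members past the threshold (1 adjusted over the list alone), CCNE2 at -0.73, MCM2 at -0.69, TYMS at -0.56 and RRM2 at -0.56, and was not called without c9t11 CLA replicate 1 (0.198). Without that array TYMS at -0.33 (adjusted p 0.085) and RRM2 at -0.30 (adjusted p 0.129) were not called.

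Lists not called still held genes that separated the isomers. ABCA1 differed by -1.82 (SE 0.16) and MYLIP by -0.99 among sterol efflux genes and LXR targets (2 higher and 4 lower of 10, list adjusted p 0.0591). Of 14 genes of calcium transport and the vitamin D response 7 were higher, with MYLK at 1.60, ITPR3 at 0.54 and VDR at 0.50 (list adjusted p 0.0591, centred 0.0376; on centred arrays adjusted p = 0.43 with an estimated correlation). CDKN1A at 1.34, CASP8 at 0.75 and MCL1 at 0.71 were higher and SESN1 at -0.90 lower among p53 and apoptosis genes (list adjusted p 0.0794, centred 0.0376; on centred arrays adjusted p = 0.43 with an estimated correlation). IFITM1 at 2.17 and OAS1 at 1.09 were higher and IFIT1 at -2.71 and IFI6 at -0.95 lower among interferon response genes (list adjusted p 0.994). MYC at 1.57 was higher, and ASCL2 at -1.22 and ZNRF3 at -1.20 lower, among Wnt and stem cell genes (list adjusted p 0.226). FOXA1 at -1.45 and GATA6 at -0.70 were lower and KLF4 at 0.65 higher among intestinal transcription factors (list adjusted p 0.273). ABCG2 at 1.18, SULT1A1 at 1.14 and CYP3A5 at 1.10 were higher among xenobiotic genes (list adjusted p 0.753), and MMP1 at 2.95 and PLAUR at 1.56 among cytoskeleton and matrix genes (list adjusted p 0.393). The cholesterol (adjusted p 0.994), fatty acid synthesis (0.664), triglyceride (0.994), metallothionein (0.684), inflammation (0.402), respiratory chain (0.393), secretory cell (0.994) and stromal (0.146) lists were not called either. Adjusted over the list alone, the higher and lower members numbered 6 and 3 for cholesterol genes, 7 and 5 for triglyceride assembly, 9 and 2 for p53 genes, 7 and 4 for xenobiotic genes, 7 and 3 for cytoskeleton genes and 4 and 4 for intestinal transcription factors. Medians, means and test directions differed in sign for the cholesterol, metallothionein, inflammation, interferon and xenobiotic lists. With the replicate block the brush border list was not called (adjusted p 0.0803, 9 higher and 4 lower) and the calcium list was placed higher (adjusted p 0.0348; adjusted p = 0.489 with an estimated correlation). With that block the higher and lower members numbered 18 and 1 for glycolysis and hypoxia, 10 and 2 for cell junctions, 2 and 4 for proliferation, 5 and 1 for cholesterol genes, 4 and 0 for fatty acid synthesis and 3 and 1 for secretory cells.

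Some genes that moved against LA were not separated between the isomers. LSS, higher with both, differed between them by 0.03 (95% interval -0.32 to 0.38), AURKA by 0.03 (-0.21 to 0.27), CCNA2 by 0.05 (-0.25 to 0.35), CDK1 by -0.06 (-0.32 to 0.20) and BUB1 by 0.21 (-0.12 to 0.55). MKI67 differed by -0.31 (-0.67 to 0.05). Of the 7736 genes that did not pass in this comparison, 7468 (96.5%) had a 95% interval within 2-fold either way and 5442 (70.3%) within 1.5-fold.

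Across the 11194 genes the fold changes of the 2 isomers against LA ran slightly in opposite directions, with Pearson's r of -0.14 and Spearman's rho of -0.07. Without LA replicate 1, 2 or 3 the r was closer to 0, at -0.0894, -0.0666 and -0.0469. Unchanged groups that share the LA arrays gave a mean r of 0.50 (0.47 to 0.53 over 100 draws). Changes with a single isomer would also bring r below that range. The covariance was -0.0154 against a simulated 0.0128, a difference of -0.0283. Of the genes called in both comparisons against LA, 46 rose with t10c12 CLA and fell with c9t11 CLA (23.9 from independent lists), among them CEACAM7, at 2.75 and -1.01, ATF3 and ARG2. A further 14 went the opposite way (7.4 from independent lists), while 2 rose with both (5.2) and 36 fell with both (33.7), among them AURKA, BUB1, CCNA2 and CDK1. On centred arrays, chosen after seeing the data, the 4 counts in this order were 18, 17, 6 and 5 (8.3, 8.2, 7.7 and 8.8 from independent lists). In 100 draws of unchanged groups that share the LA arrays each count was at most 1, as almost no gene is called without an effect, so this value does not bear on the directions. Independent lists leave out the shared LA arrays, which are too few to be split.

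Array controls for RNA quality were compared by exact two-sided permutation tests, which with 3 against 3 arrays cannot give a p below 0.1. The log2 ratio of 3-prime to 5-prime control signals for GAPDH was -0.07 ± 0.03 with t10c12 CLA, -0.11 ± 0.02 with LA and -0.14 ± 0.02 with c9t11 CLA (SD, n = 3; exact permutation p of 0.2, 0.2 and, between the isomers, 0.1). For ACTB it was 1.11 ± 0.17, 1.16 ± 0.08 and 1.24 ± 0.03 (exact permutation p of 0.8 for t10c12 CLA against LA, 0.2 for c9t11 CLA against LA and 0.4 between the isomers). The GAPDH ratios of the isomers did not overlap, at -0.091 to -0.035 with t10c12 CLA and -0.154 to -0.118 with c9t11 CLA. A difference in RNA quality between the isomers therefore stays open.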

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

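The tests of the scale of the c9t11 CLA arrays and of a single axis of cell state were chosen only after the results they bear on were seen, as were quantile normalization together with the stricter filter, the condition that fry with the replicate block must call a list in both comparisons, with and without centring, and the comparison with splits that part the labelled pairs. Of 3992 probe sets that name several genes or none and pass the intensity filter, 144 differed for t10c12 CLA against LA, 69 higher and 75 lower, 178 for c9t11 CLA against LA, 46 higher and 132 lower, and 845 between the isomers, 566 higher and 279 lower with t10c12 CLA, signals outside the genes the comparisons use.

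The calls for c9t11 CLA against LA lean to lower values and to dim genes. RNA quality stays open. For 0 of the 2 control genes did the 3-prime to 5-prime ratio set the c9t11 CLA arrays apart from LA. The difference in log2 ratio was -0.036 for GAPDH and 0.082 for ACTB, each with an exact permutation p of 0.2. With 3 against 3 arrays that p cannot go below 0.1, so these ratios cannot exclude a difference in quality. A lower scale of the c9t11 CLA arrays goes with the lean to lower values. Their 95th percentile of intensity over all probe sets but controls was 767 to 773. It was 839 to 866 with LA and 838 to 857 with t10c12 CLA. With centred arrays 51.8% of the calls were lower, against 82.1% as fitted. These values do not tell the handling of the arrays from the fatty acid, so the source of the lower scale stays open. The hybridisation spikes differed from those of LA by a log2 of 0.10 (95% interval -0.33 to 0.53), too wide to tell no shift from the median shift of -0.13. A different background step may account for the dim calls, since 36.83% of the probe sets too dim to test had all 3 c9t11 CLA values on one side of the other 6 arrays, above the 5.18% of t10c12 CLA and 2.47% of LA. Whether the fatty acid itself changed total RNA or dim transcripts was not tested and stays open.

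The fold changes of the isomers against LA ran slightly in opposite directions across genes, with Pearson's r of -0.14 and Spearman's rho of -0.07. After quantile normalization with the filter at a log2 of 6, r stayed negative, at -0.1156. It was at most -0.0469 when each LA array was left out in turn. For the negative sign, these values argue against a single LA array as the whole cause. An even shift of scale cannot change r, which was -0.1407 with and without centring. The background of the c9t11 CLA arrays stays open, since rescaling does not undo a change that differs between probe sets. These arrays still stood apart at 11.02% of the genes with a mean log2 above 8. Unchanged groups gave an r of 0.4738 or more with quantile normalization and that filter. Without single LA arrays they gave 0.5758 or more. Those draws hold no change in any gene, while 1601 genes differed for t10c12 CLA against LA, so the gap to their r decides nothing. One shared axis of cell state, with the isomers on either side of LA, stays open. The first principal component placed the LA arrays between those of the isomers. It comes from the same arrays and genes as r, so it is no separate support for such an axis. Of 5 lists called against LA for both isomers, 3 went the same way (cholesterol, fatty acid synthesis, proliferation) and 2 opposite ways. The 3 speak against such an axis only weakly, since the shared LA arrays by themselves favour calls that go the same way. None of the calls of these lists held with an estimated correlation (for the 3 lists adjusted p = 0.297, 0.265 and 0.297 with t10c12 CLA and 0.297, 0.297 and 0.660 with c9t11 CLA). With the replicate block 23 of 25 proliferation genes were lower with t10c12 CLA and 21 with c9t11 CLA (21 and 7 on centred arrays). Fry with the block missed the threshold for each of the 3 lists with c9t11 CLA (adjusted p 0.118, 0.363 and 0.0681). With t10c12 CLA it missed it for cholesterol (0.063) and fatty acid synthesis (0.0863) and passed for proliferation (0.0309). With centring as well it passed with both isomers for cholesterol and proliferation (0.0277 to 0.0479). So it did for glycolysis, which went opposite ways (7.49e-05 and 0.0479). Fatty acid synthesis then missed with c9t11 CLA (0.175), and liver-type proteins missed with t10c12 CLA (0.0557) and c9t11 CLA (0.55). An opposite effect of the isomers on a shared set of genes is a hypothesis found and tested on the same data.

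Other splits of the arrays bear on each count. For t10c12 CLA against LA, with the 6 arrays alone, 1 of the 10 splits into 3 and 3, the real one, gave as many as its 1309 genes, and the highest of the others gave 0. For c9t11 CLA against LA it was again 1 of 10, with 340 genes against at most 10, and for t10c12 CLA against c9t11 CLA 1 of 10, with 3243 against 0. In each comparison 4 of the 10 splits, the real one included, part the arrays numbered 2 and those numbered 3, and the others of these 4 gave 0 genes, while the remaining splits keep at least 1 such pair together. These splits are too few for a share under 0.05. For the F test 1 of 100 drawn splits of the 9 arrays into 3 groups, the real one, gave as many as 3212 genes, and the highest of the others gave 1434. That share leaves out the pairing of the numbered arrays, so it cannot exclude chance as the source of the count. Of the 100, 12 part the arrays of each labelled number as the real one does, the highest of the others again at 1434, and 12 are too few for a share under 0.05.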

How the results depend on the processing

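The quantile normalization with the stricter filter, the rescaled gene lists, the block on centred arrays and fry with the block were chosen after seeing the data. For t10c12 CLA against LA the 1601 genes became 1009 with no filter, 993 with a change of at least 1.5-fold, 629 at an adjusted p under 0.01, and 1001 to 1543 with 1 array left out, all other settings staying within 1.5 times. For t10c12 CLA against c9t11 CLA the 3458 became 5411, 1851 and 1736 under the same 3 settings, 2242 with quantile normalization and the stricter filter, and 2448 to 3479 with 1 array left out. The F test's 3212 became 4832 with no filter, 1412 at 0.01, 2023 with quantile normalization and the stricter filter, and 2164 to 3037 with 1 array left out. For c9t11 CLA against LA the 491 became 2454 with no filter, 71 with the stricter filter, 944 with every probe set tested, 1134 with array weights, 216 with quantile normalization, 226 with centring, 316 at 1.5-fold, 45 at 0.01, 1174 at 0.1, 0 in limma with quantile normalization and the stricter filter (1047 at an unadjusted p under 0.05), and 80 to 499 with 1 array left out. A replicate block on the labelled numbers 2 and 3, with 6 arrays, gave 1794, 812 and 3156 genes in the 3 comparisons, and beside the calls for which its values stand in the results it changed no other call of a list or gene given there. With that block on centred arrays the counts were 1646, 133 and 2904, and 86 of 88, 26 of 41 and 101 of 105 named genes called kept their call. For t10c12 CLA against LA the p53 list then missed the threshold (adjusted p 0.0597). The Wnt list was placed lower there (adjusted p 0.0359, or adjusted p = 0.44 with an estimated correlation). The same block over all 9 arrays, with the unnumbered array of each CLA group taken as number 1, gave 2191, 975 and 4160. The gene lists called went from 11, 8 and 9 to 0 in each comparison in camera with an estimated correlation (3, 3 and 1 at an unadjusted p under 0.05) and to 15, 1 and 15 with fry, which called 9, 0 and 8 of the same lists, its 1 for c9t11 CLA being the calcium list (lower, adjusted p 0.0324). With fry and the replicate block they numbered 7, 0 and 12, the xenobiotic list for c9t11 CLA turning to lower (adjusted p 0.764), and on centred arrays 13, 4 and 10. The 8 for c9t11 CLA became 5 with no filter, with quantile normalization and with centring. With 1 array left out the lists numbered 10 to 12, 5 to 9 (5 without LA replicate 3 or c9t11 CLA replicate 2) and 5 to 10 (5 without c9t11 CLA replicate 1). The correlation between the isomers stayed negative, from -0.0894 to -0.0469 without single LA arrays. Of the named genes called, 75 of 88, 15 of 41 and 86 of 105 kept the call in every other setting that weighed them, and 78, 17 and 93 with each array left out. Other thresholds and the test of every probe set were not weighed there. Nor was a setting whose filter removed the gene, as the stricter filter did with APLP1, KCNN1 and GPR132. HMGCS1 between the isomers turned to 0.02 with the mean of its probe sets, whose members disagree. The cause of the other shifts was not tested. Signal over background limits the sizes of changes near an intensity of 16. Genes with a mean log2 below 5 made up 10.7%, 39.3% and 17.2% of the calls in the 3 comparisons, and 10%, 11.2% and 34.7% of them were called, against 17.1%, 2.9% and 33.5% of those above 8.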
